A study of Homo sapiens with 6 samples.

How the data were processed

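Poly(A) RNA of DLD-1 cells, a human colorectal adenocarcinoma line, was sequenced in 6 libraries, 3 from cells given TGF-β (TGFb 1 to 3) and 3 from cells given TGF-β and TFA, the total flavones of the plant Abelmoschus manihot (TGFb_TFA 1 to 3). Per the labels' protocols, the libraries kept strand by dUTP labelling and carried unique molecular identifiers in their adapters. Whether these identifiers were used to remove duplicates is not given in the sources used here. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d and the build GRCh38, with no role given for each. The deposited table holds 31016 genes, with an FPKM value and an estimated count per library as the authors made them. It also gives each gene a position, a name, and GO and KEGG terms. Clone-based names stand there without their version number, and 4446 genes share a name with another one, so the gene identifier is given beside such names.

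The deposited estimated counts are whole numbers, but they may have been derived from coverage rather than counted read by read. In single-exon genes, 99.7% to 100% of counts per library equalled FPKM times length times a constant, within 1 count or 1%. A count of 4 was found in 1032 to 1271 genes per library, more than a count of 3 (601 to 685) or 5 (345 to 396). A single fragment therefore probably adds about 4 counts, and the totals overstate the number of fragments. The total per library was 60361756 to 68745953 estimated counts. Deposited FPKM values already correct for transcript length and library total, so depth cannot be read from them.

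The main comparison used the estimated counts in edgeR 4.0.16 (R 4.3.3): genes passing filterByExpr, TMM scaling, a quasi-likelihood fit with group as the only term, glmQLFTest (2-sided), and Benjamini-Hochberg adjustment over 18265 genes. A gene was called at an adjusted p under 0.05, with no fold threshold. Standard errors are the fitted log2 fold change divided by the square root of the test's F, and intervals are 95%. Expression levels are given as FPKM, mean ± SD of 3 libraries, or as CPM, the depth-scaled counts of edgeR on the TMM-scaled library size. Genes chosen by rule were the 10 largest rises and 10 largest falls among called genes with a mean FPKM of at least 1 in the higher group and groups that do not overlap, filled by lowest unadjusted p where fewer qualified. The rule also took a fixed set of STAT3, TGF-β, EMT (epithelial-mesenchymal transition) and apoptosis genes, the lncRNA AL137782, and members of lists that were called. Other genes are said to have been chosen after their values were seen.

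Lists of genes (38 lists, all with at least 5 tested members) were tested with camera in limma 3.58.1, at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction, were run beside it. GO and KEGG terms of 10 to 500 tested genes were tested by a one-sided Fisher exact test for each direction, against the 13778 tested genes with a term. The tests, groups, gene lists and most alternatives were fixed before the data were examined. The plan made edgeR the main test if the table held raw counts, and limma-trend on FPKM otherwise. Treating the estimated counts as such counts was a choice made with the table in hand.

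The alternatives were limma-trend on log2(FPKM + 0.5) with other pseudocounts (0.1 and 1), scalings (median, quantile, TMM on FPKM) and variance models, no filter or a mean FPKM of at least 5, DESeq2's size factors in edgeR, the DESeq2 1.42.0 Wald test, a fold threshold, the replicate number as a block, and leaving out each library in turn. Added after seeing the data were offsets that remove each library's trend along effective transcript length, readthrough genes summed with their partners (100 groups of 305 genes), counts divided by 4, TGFb 1 and TGFb_TFA 3 left out together, and the AhR list without CYP1A1. Effective length was the ratio of count to FPKM. Exons shared between overlapping genes were measured in GENCODE 29, which holds 97.3% of the table's identifiers, with the same coordinates for 57.0% of those found; positions printed here are the table's own.

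Simulated data held 200 changed genes among 18265, all drawn from genes with a mean CPM of at least 2. Each gene's spread between libraries was taken from the trend over expression level, not from the gene itself. There edgeR called 1.5% of genes changed 1.5-fold, 57.5% of those changed 2-fold, 99.5% of those changed 4-fold and 100% of those changed 16-fold. In the same simulation of 2-fold changes, 22.7% of DESeq2's calls and 4.96% of edgeR's were genes that had not been changed. Libraries of a group differed by more than sampling noise: the lowest chi-square per degree of freedom between a pair was 12.4 on the estimated counts, or 3.10 if each fragment adds 4. The labels give the libraries numbered 1, 2 and 3 treatment times of 24, 25 and 26 h in both groups, while the study's own design text gives 24 h. Nothing says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. There was no library without TGF-β, and the effect of TGF-β itself was not analysed here.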

Results

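RNA was measured in DLD-1 cells given TGF-β alone (3 libraries) or TGF-β and TFA, a flavonoid extract (3 libraries). TGF-β is a growth factor used to drive epithelial cells towards a mesenchymal state. The study asked whether TFA counters migration and survival of these cells, and its title names STAT3, EMT and the lncRNA AL137782. The only comparison of the design is therefore TGF-β with TFA against TGF-β alone. Total estimated counts ran from 60361756 (TGFb_TFA 3) to 68745953 (TGFb 1), and 23096 to 24159 genes were above 0 per library. TGFb_TFA 3 stood apart by transcript length: its shortest 10% of genes lay at a median of 0.43 above the mean of the 6 libraries (log2) and its longest 10% at -0.44. In the other 5 libraries both medians lay within -0.19 and 0.20. Among them only TGFb 2 shared the direction of TGFb_TFA 3, more weakly (0.11 for the shortest genes and -0.19 for the longest). TGFb 1 stood apart on the first principal component (35.7% of variance).

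**Figure D1:**
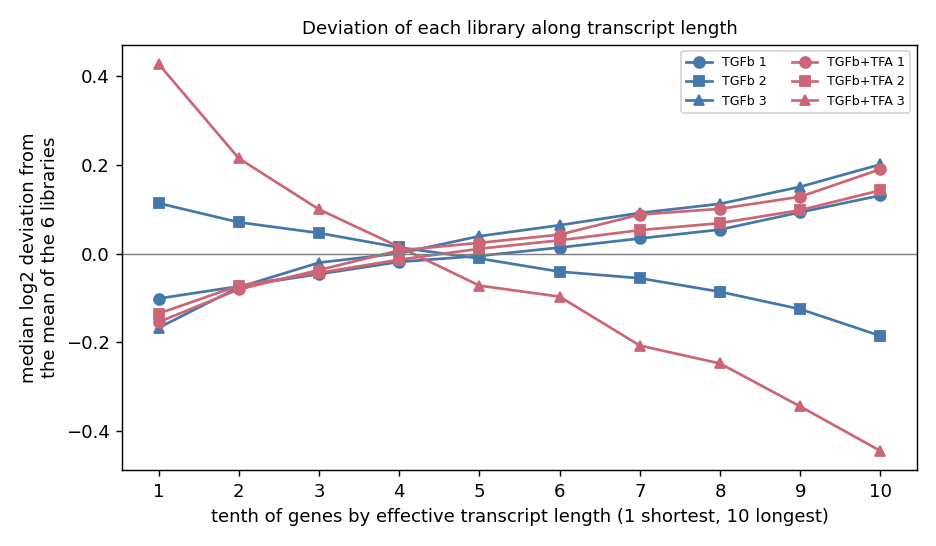
Median log2 deviation of each library from the mean of the 6 libraries (y) for 10 equal groups of genes ordered by effective transcript length (x), blue for TGF-β and red for TGF-β with TFA. TGFb_TFA 3 runs from 0.43 in the shortest group to -0.44 in the longest.

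CYP1A1, the cytochrome P450 enzyme whose transcription is the classic readout of the aryl hydrocarbon receptor (AhR), rose with TFA. Its level went from 0.50 ± 0.10 FPKM to 22.5 ± 1.70 FPKM (SD, n = 3), and its counts from 134, 101 and 143 to 5462, 5360 and 4727. The fitted log2 fold change was 5.50 (SE 0.18; 95% interval 5.07 to 5.93), a 45.3-fold rise, with an adjusted p of 6.93e-05 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. CYP1A1 (ENSG00000140465) lies on chromosome 15 from 74719542 to 74725536 on the minus strand (GRCh38).

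Over the whole list of AhR targets, CYP1A1 was called among 13 tested members over all genes, and 4 were higher when adjusted over the list alone: CYP1A1, TIPARP, CYP1B1 and ABCG2. TIPARP, an ADP-ribosyltransferase that feeds back on AhR, had a log2 fold change of 0.71 (SE 0.13). CYP1B1, a related P450, had 0.99 (SE 0.20), and ABCG2, an efflux transporter, had 0.68 (SE 0.15). Over all genes none of these 3 passed (adjusted p = 0.9997 each, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), although in each of them all TFA libraries lay above all TGF-β libraries. DESeq2 called CYP1B1 (adjusted p = 0.0180) and TIPARP (adjusted p = 0.0364) higher, and not ABCG2. Values of NQO1 (0.27), AHRR (0.18), ALDH3A1 (0.23) and AHR itself (-0.17) did not pass in either family. As a set the list was higher (median log2 fold change 0.23, camera adjusted p = 1.81e-26), and this held with an estimated correlation (adjusted p = 0.0118) and by fry (adjusted p = 0.00580). Leaving out TGFb_TFA 1 raised the median to 0.36. Without CYP1A1, a choice made after seeing the data, the other members had a median of 0.20 and an adjusted p of 6.75e-05 by camera, or adjusted p = 0.182 with an estimated correlation.

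**Figure D2:**
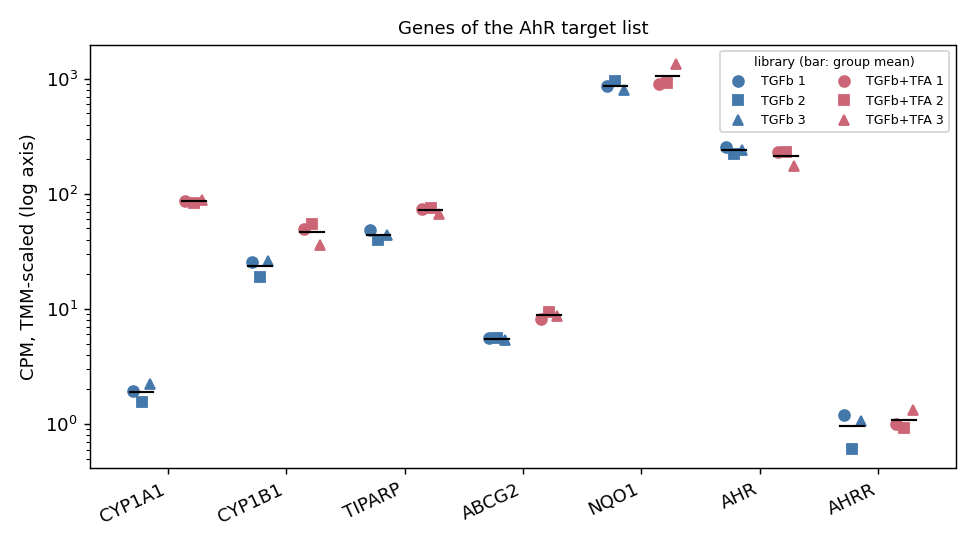
CPM on the TMM-scaled library size (log axis) of 7 members of the AhR target list in each library, blue for TGF-β, red for TGF-β with TFA, bars for group means. CYP1A1 is separated by a 45.3-fold change, CYP1B1, TIPARP and ABCG2 by less, and NQO1, AHR and AHRR overlap.

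STBD1, which encodes a glycogen-binding protein, was the other called gene. It rose from 2.29 ± 0.469 FPKM to 10.3 ± 0.565 FPKM (SD, n = 3), a log2 fold change of 2.20 (SE 0.18) with an adjusted p of 0.0255 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. STBD1 (ENSG00000118804, chromosome 4, 76306026 to 76311599, plus strand) overlaps the readthrough gene FAM47E-STBD1, with which it shares 1986 exon bases. FAM47E-STBD1 went the other way, from 9.57 ± 1.40 FPKM to 0.711 ± 0.655 FPKM (log2 fold change -3.71, SE 0.84, not called). Counts summed over STBD1 and FAM47E-STBD1 differed by -0.02 on the log2 scale (95% interval -0.33 to 0.29, not called). FAM47E-STBD1 also shares 1097 exon bases with FAM47E, which had a log2 fold change of 0.88 (SE 0.19, not called). Counts summed over STBD1, FAM47E-STBD1 and FAM47E differed by 0.18 (95% interval -0.12 to 0.49, not called). Leaving out 1 library kept the STBD1 call only without TGFb_TFA 3 (adjusted p = 0.0283) and lost it without TGFb 1, 2 or 3 (0.237, 0.162 and 0.0642) or TGFb_TFA 1 or 2 (0.0839 and 0.105), with log2 fold changes of 2.08 to 2.32 in these 6 fits. With the replicate number as a block the STBD1 call was lost as well (log2 fold change 2.22, adjusted p = 0.315). The CYP1A1 call held without each library in turn (highest adjusted p = 0.00368; all of these by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment).

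**Figure D3:**
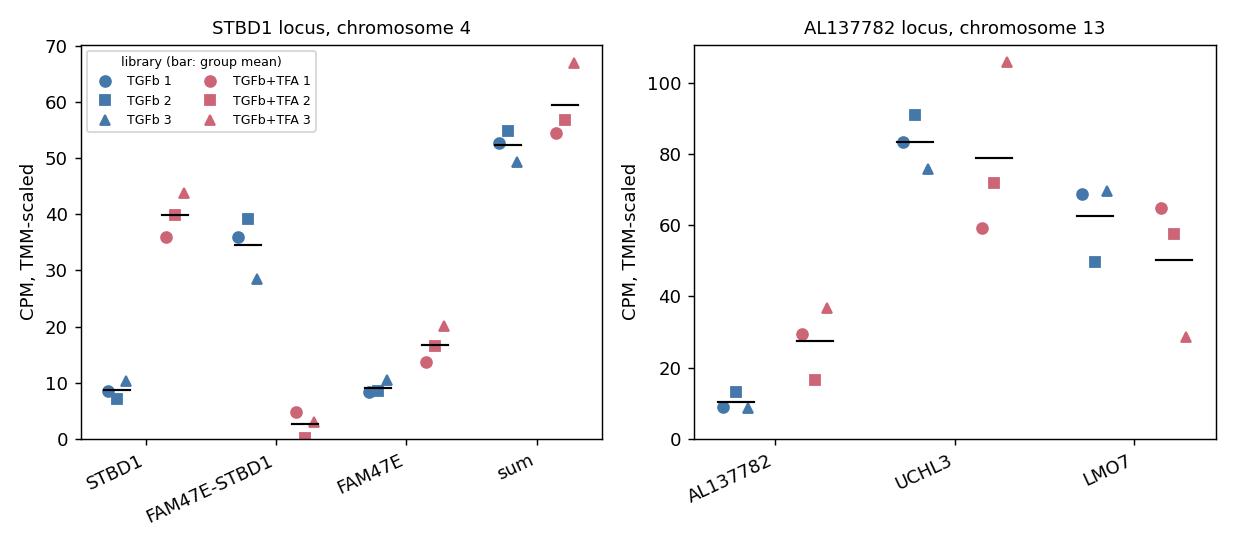
CPM on the TMM-scaled library size of overlapping genes in each library, blue for TGF-β, red for TGF-β with TFA, bars for group means. STBD1 is higher and FAM47E-STBD1 lower with TFA while the sums of the 3 genes overlap between the groups, and AL137782 is higher while UCHL3 and LMO7 overlap.

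No gene was called lower by edgeR. At an unadjusted p under 0.05 there were 195 genes higher and 139 lower among 18265, where 913 in all would be expected by chance, and DESeq2 called 13 higher and 2 lower. With TGFb 1 and TGFb_TFA 3 left out together, edgeR gave 823 of 18644 genes at an unadjusted p under 0.05. The count thus depended on these libraries and does not show how many genes changed. Groups did not overlap in 7.91% of genes, against 10% by chance. Genes next in order that did not pass included, on the higher side, VIM (log2 fold change 2.17, SE 0.49), FAM47E (0.88, SE 0.19), NANOS1 (0.66, SE 0.16) and GPR89B (0.66, SE 0.18). On the lower side stood CLDN2, a tight junction protein (-0.60, SE 0.14), SULT2B1, a sulfotransferase for steroids (-0.67, SE 0.16), KLK10, a secreted protease (-0.53, SE 0.13), and GSN, the actin-severing gelsolin (-0.48, SE 0.12). TNFRSF10D, a decoy receptor for the death ligand TRAIL, had -0.51 (SE 0.14), AC138811 (ENSG00000260342) -1.18 (SE 0.30), MAB21L4 -0.58 (SE 0.16), SCEL -0.81 (SE 0.23) and AMACR -0.39 (SE 0.11). Each of these 13 genes had an adjusted p of 0.9997 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment.

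The lncRNA named in the title, AL137782 (ENSG00000261553, chromosome 13, 75549773 to 75807120, plus strand), had 2.21 ± 0.521 FPKM with TGF-β and 5.73 ± 1.78 FPKM with TFA added (SD, n = 3). Its counts were 627, 871 and 559 against 1851, 1077 and 1982, so all 3 TFA libraries lay above all TGF-β libraries. The fitted log2 fold change was 1.42 (SE 0.31; 95% interval 0.70 to 2.14), with an unadjusted p of 0.00209. It did not pass in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.9997), and did in DESeq2 (adjusted p = 0.0107). AL137782 shares 580 of its 4178 exon bases with UCHL3 and 1283 with LMO7, both on its strand. UCHL3 had a log2 fold change of -0.08 (SE 0.22) and LMO7 of -0.32 (SE 0.30).

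STAT3 itself, the transcription factor of the title, was at 4.11 ± 0.438 FPKM with TGF-β and 3.65 ± 0.998 FPKM with TFA added (log2 fold change -0.16, 95% interval -0.57 to 0.25). Its feedback inhibitor SOCS3 (0.34, interval -1.18 to 1.86) and the kinases JAK1 (-0.10, interval -0.49 to 0.29) and JAK2 (-0.28, interval -1.05 to 0.49) did not pass either. RNA levels of STAT3 and these kinases do not measure the activity of the proteins. Of 25 tested members of the STAT3 list, none was called or passed when adjusted over the list alone (edgeR), and 0 had an unadjusted p under 0.05. The list's median was -0.10 and its mean 0.02, and camera gave a lower direction with an adjusted p of 0.311. Leaving out 1 library gave STAT3 list medians from -0.16 (without TGFb_TFA 1) to -0.0028 (without TGFb_TFA 3).

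Among 25 tested members of the mesenchymal EMT list, 19 had fitted values above 0 and 8 had an unadjusted p under 0.05, all higher with TFA, while none was called over all genes or adjusted over the list alone (edgeR). VIM, the mesenchymal intermediate filament vimentin, went from 0.526 ± 0.283 FPKM to 2.39 ± 1.15 FPKM (SD, n = 3), and DESeq2 called it (adjusted p = 0.00111). The matrix protein FN1 (1.02, interval 0.02 to 2.02), the protease MMP2 (2.48, interval 0.47 to 4.48), COL1A1 (2.93, interval 0.58 to 5.28) and COL1A2 (2.85, interval 0.13 to 5.57) had wide intervals, and COL1A2 had no count in TGFb 1. The values of FN1 and MMP2 rested mainly on TGFb_TFA 2. FN1 had 444, 1461 and 501 counts in TGFb_TFA 1 to 3, against 366 to 532 with TGF-β. MMP2, at a mean of 0.053 FPKM with TGF-β and 0.299 FPKM with TFA, had 14, 211 and 68 counts against 12 to 22. The most abundant members were S100A4 (-0.12, SE 0.21) and CTHRC1 (0.49, SE 0.18). CDH2 (0.28), SNAI1 (0.24) and ZEB1 (0.42) had intervals that held 0, and TWIST1 and MMP9 were too low to test. As a set the list was higher (median 0.49, camera adjusted p = 6.55e-09), but adjusted p = 0.337 with an estimated correlation. In the fits on FPKM only 6 members were high enough to test, with medians of 0.15 to 0.22, and in edgeR the same 6 had a median of 0.23. TGFb 1 held the lowest value of VIM, COL1A1 and COL1A2 (87, 4 and 0 counts), and without it and TGFb_TFA 3 the list was still called (median 0.51, adjusted p = 2.75e-04).

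Fibroblast markers (8 tested members, all fitted above 0, 4 at an unadjusted p under 0.05, none called by edgeR and COL6A3 called by DESeq2, adjusted p = 0.0343) had a median of 1.91 and a camera adjusted p of 6.29e-09, or adjusted p = 0.182 with an estimated correlation. Without 1 library the fibroblast median ran from 1.70 (without TGFb_TFA 3) to 2.91, 3.13 and 3.37 (without TGFb 2, TGFb 3 and TGFb_TFA 1). COL1A1 is in both lists. Endothelial markers (7 tested members, none called by edgeR) had a median of 0.94 and a camera adjusted p of 0.00400, or adjusted p = 0.337 with an estimated correlation; their most abundant members were EGFL7 (0.24, SE 0.18) and ESAM (0.48, SE 0.40). Without TGFb 1 and TGFb_TFA 3 the endothelial call was lost (median 0.56, adjusted p = 0.124), as it was without TGFb_TFA 3 alone (median 1.01, adjusted p = 0.0649), and the fibroblast call was not (adjusted p = 6.71e-04). Haematopoietic markers were not called (6 tested members, adjusted p = 0.468). The epithelial EMT list (31 tested members, none called, 22 fitted below 0) was lower at a median of -0.10 with a camera adjusted p of 0.0430, or adjusted p = 0.337 with an estimated correlation. CDH1, the E-cadherin gene, had -0.26 (interval -0.92 to 0.39), and the keratins KRT18 and KRT8 had -0.14 (SE 0.19) and -0.06 (SE 0.15). The epithelial call was lost without TGFb 2, TGFb 3 or TGFb_TFA 3 (medians -0.10, -0.09 and 0.0054, adjusted p = 0.114, 0.149 and 0.140).

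**Figure D4:**
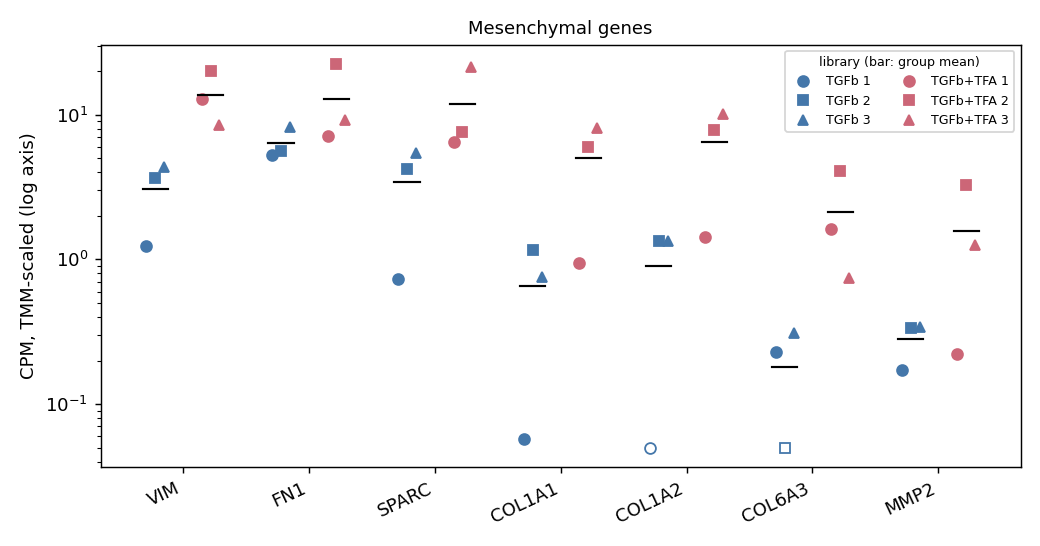
CPM on the TMM-scaled library size (log axis) of 7 mesenchymal genes in each library, blue for TGF-β, red for TGF-β with TFA, bars for group means and open symbols at the bottom for a count of 0. The TFA libraries differ among themselves, with 803, 1300 and 459 counts of VIM.

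In the lists for migration and apoptosis, the outcomes the study asked about, no gene was called by edgeR. RNA levels do not measure these outcomes themselves. The migration and invasion list (30 tested members, 1 at an unadjusted p under 0.05) had a median of -0.06, a mean of 0.06 and a camera adjusted p of 0.441. The lists of genes that promote and oppose apoptosis had medians of 0.06 and -0.05 and camera adjusted p values of 0.441 and 0.294, with 0 of 26 and 0 of 17 members called by edgeR and 0 at an unadjusted p under 0.05. Without 1 library their medians ran from -0.022 to 0.093 and from -0.12 (without TGFb_TFA 2) to -0.03 (without TGFb 3), and that of migration from -0.10 to 0.03. BAX (0.14, interval -0.21 to 0.50) and BCL2 (0.22, interval -0.47 to 0.91) did not pass, nor did the proliferation marker MKI67 (-0.10, interval -1.37 to 1.16). The TGF-β SMAD list (29 tested members, none called) had a median of -0.03 and a camera adjusted p of 0.327, but was called lower without TGFb 1 (median -0.05, adjusted p = 0.0330), and its median was -0.11 without TGFb_TFA 1 and -0.10 without TGFb_TFA 2. SMAD3 (-0.20), SMAD7 (0.17), TGFB1 (-0.31) and TGFBR2 (-0.12) had intervals that held 0.

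Another 6 lists were called by camera with no member called by edgeR, and each lost its call with an estimated correlation. Hypoxia targets of HIF were lower (26 tested members, 18 fitted below 0, 5 at an unadjusted p under 0.05, median -0.15, camera adjusted p = 5.43e-04, or adjusted p = 0.337 with an estimated correlation). Their most abundant members, DDIT4 (-0.02, SE 0.16) and P4HA1 (-0.19, SE 0.12), did not pass. Cholesterol synthesis genes were lower (24 tested members, 18 fitted below 0, median -0.15, adjusted p = 0.00295, or adjusted p = 0.235 with an estimated correlation, and 0.00580 by fry), with FDPS at -0.14 (SE 0.19) and FDFT1 at -0.11 (SE 0.16). Without TGFb 2 or TGFb_TFA 1 the cholesterol median was -0.10. Immediate early genes were lower (28 tested members, 24 fitted below 0, median -0.11, adjusted p = 0.00812, or adjusted p = 0.709 with an estimated correlation), with IER3 at 0.03 and DUSP6 at -0.09. Their call was lost without TGFb 3 (median -0.08, adjusted p = 0.378) or TGFb_TFA 3 (median -0.05, adjusted p = 0.319), and the median was -0.17 without TGFb 1 or TGFb_TFA 1. Antioxidant targets of NRF2 were higher (30 tested members, 21 fitted above 0, median 0.16, adjusted p = 0.0471, or adjusted p = 0.337 with an estimated correlation), with PRDX1 at 0.15 and TXN at 0.35. The NRF2 call was lost without each library in turn (adjusted p = 0.0550 to 0.252), with medians from 0.05 (without TGFb_TFA 3) and 0.09 (without TGFb 1) to 0.21 (without TGFb_TFA 1).

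Mitochondrially encoded genes were lower (13 tested members, 11 fitted below 0, median -0.23, adjusted p = 6.59e-04, or adjusted p = 0.580 with an estimated correlation), with MT-CO2 at -0.04 and MT-CO3 at 0.11. Their call was lost without TGFb 2 (median -0.12, adjusted p = 0.0550) or TGFb_TFA 2 (median -0.11, adjusted p = 0.104), and the median was -0.38 without TGFb 1. With quantile normalization of FPKM it was -0.06 and not called (adjusted p = 0.118), and with TGFb 1 and TGFb_TFA 3 left out it was -0.46. Ribosomal protein genes were higher (54 tested members, 53 fitted above 0, median 0.22, adjusted p = 6.59e-04, or adjusted p = 0.726 with an estimated correlation), with RPS12 at 0.23 (SE 0.27) and RPS18 at 0.25 (SE 0.29). This direction depended on TGFb_TFA 3, the library with the length trend. Without it the median was -0.14, and camera at the preset correlation called the list lower (adjusted p = 6.11e-08). The correlation estimated for this list over all libraries was 0.99, far above the preset one, so that p-value does not establish a fall. The ribosomal call was also lost without TGFb 3 (median 0.10, adjusted p = 0.689), and the median was 0.34 to 0.37 without TGFb 2, TGFb_TFA 1 or TGFb_TFA 2.

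**Figure D5:**
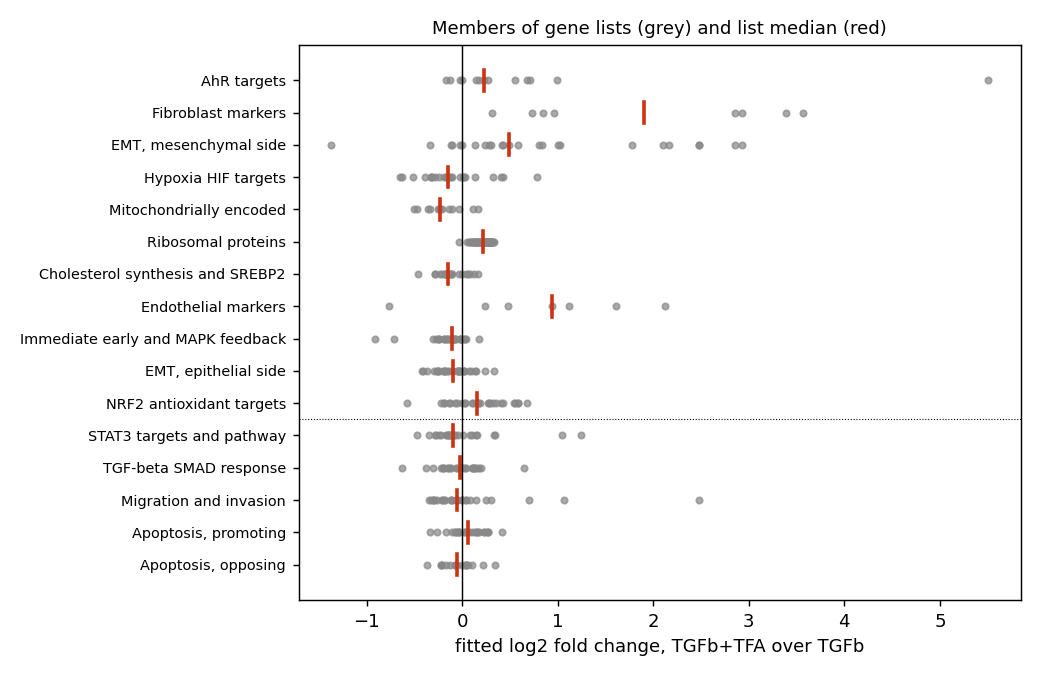
Fitted log2 fold change (x) of each tested member of the 11 called lists (above the dotted line) and of 5 lists of the study's question (below it), with the list median in red. The AhR list holds the highest value, 5.50 for CYP1A1, and the fibroblast list a median of 1.91 over all 6 libraries.

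The other 21 lists were not called: nuclear oxidative phosphorylation (adjusted p = 0.0705), Wnt (0.0799), intestinal differentiation (0.110), glycolysis (0.127), ferroptosis (0.154, but 0.0353 by fry), unfolded protein response (0.239), fatty acid synthesis and autophagy (0.260 each), YAP and histones (0.294 each), interferon (0.327), metallothioneins, ATF4, and drug metabolism (0.441 each), NF-kB (0.460), heat shock (0.645), MYC (0.655), iron, p53 and G1/S (0.746 each) and G2/M (0.781). Oxidative phosphorylation was called higher without TGFb 2 (0.00210), TGFb_TFA 1 (2.72e-04) or TGFb_TFA 2 (3.05e-04), and lower without TGFb_TFA 3 (median -0.13, adjusted p = 1.14e-04). These calls are from camera at the preset correlation of 0.01, while the correlation estimated for that list over all libraries was 0.85. Glycolysis was called lower without TGFb 1 (0.0308) or TGFb_TFA 3 (0.00380). Wnt was called lower without TGFb 1 (0.0193), TGFb_TFA 1 (0.0444) or TGFb_TFA 2 (0.0466), and metallothioneins without TGFb 1 (0.00844). Of the drug metabolism list, ABCG2 was higher and SULT2B1 lower when adjusted over the list alone. Medians and means of the NF-kB, YAP and heat shock lists differed in sign. Of 3930 GO and KEGG tests none passed (lowest adjusted p = 0.606), with 2 called genes to test and 0 on the lower side.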

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

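The settings named as added in the processing section were chosen after seeing the data. CYP1A1 was called under every alternative run. The 2 genes called higher became 13 by the DESeq2 Wald test, which also called 2 lower, and became 1 with the replicate number as a block and 1 with readthrough genes summed; without 1 library the count ran from 1 to 3. With TGFb 1 and TGFb_TFA 3 left out together 1 gene was called lower. The adjusted p of STBD1 ran from 1.33e-22 (DESeq2) to 0.315 (block), with 0.154 when TGFb 1 and TGFb_TFA 3 were left out. Correlations of same-numbered libraries' deviations were 0.04, -0.12 and -0.13, which gives no sign of pairing by number. They cannot exclude a shared culture or day, since TGFb 1 and TGFb_TFA 3 stood apart and libraries of unlike number were not compared. In the simulation edgeR called 57.5% of 2-fold and 1.5% of 1.5-fold changes, so changes under 2-fold were mostly out of reach even there. The simulated libraries had neither the length trend of TGFb_TFA 3 nor the deviation of TGFb 1. The shares called may therefore be lower in the real data, and larger changes may have been missed too. In the main fit STBD1, at 4.61-fold, was called. VIM at 4.49-fold and COL1A1 at 7.61-fold were not, nor was FAM47E-STBD1, which was 13.1-fold lower with TFA. The number of lists called (11) became 1 with an estimated correlation and 3 by fry, reached 15 of 31 at a mean FPKM of at least 5, and ran from 7 without TGFb 3 to 14 without TGFb 1. AhR targets were called under each setting over the whole list, and lost the call with CYP1A1 left out and an estimated correlation (median 0.20). Glycolysis, Wnt and fatty acid synthesis were called lower in each fit on FPKM, and oxidative phosphorylation higher in each but the quantile one. The mesenchymal list (0.49, or 0.15 to 0.22 on FPKM with 6 members) lost its call with an estimated correlation and by fry, as did the epithelial list (-0.10), which also lost it on FPKM at pseudocount 0.1 (-0.11) and with TMM factors (-0.070), and with both libraries left out (-0.048); without 1 library it ran from -0.10 to 0.0054. STAT3 targets were called lower at a mean FPKM of at least 5 (-0.13). Migration was called lower on FPKM with pseudocount 1 (-0.11), median scaling (-0.065), quantile normalization (-0.12) and TMM factors (-0.076), and ran from -0.10 to 0.034 without 1 library. The TGF-β SMAD list was called lower without TGFb 1 and ran from -0.11 to -0.0036. The apoptosis-promoting list ran from -0.022 to 0.093 and was at -0.000423 with both libraries left out. Ribosomal protein genes ran from -0.14 to 0.37, and were at -0.18 with both left out. AL137782 had 1.41 in DESeq2, where it passed, and kept its sign in each setting. The remaining sign changes were in genes that passed in no setting. Without 1 library CDH1 ran from -0.46 to 0.0054, JAK2 from -0.499 to 0.038, MKI67 from -0.42 to 0.31, JAK1 from -0.21 to 0.020, TGFBR2 from -0.25 to 0.043 and SMAD3 from -0.40 to 0.037. In the same way S100A4 ran from -0.37 to 0.0018, KRT18 from -0.32 to 0.014, KRT8 from -0.18 to 0.021, PRDX1 from -0.088 to 0.25, TXN from -0.063 to 0.51, DDIT4 from -0.16 to 0.067 and IER3 from -0.057 to 0.11. MT-CO2 ran from -0.26 to 0.054, MT-CO3 from -0.17 to 0.24, RPS12 from -0.15 to 0.39 and RPS18 from -0.18 to 0.41. With both libraries left out, values were BAX -0.058, JAK2 0.084, SNAI1 -0.13, MKI67 0.47, JAK1 0.065, TGFBR2 0.12, CDH2 -0.062, SOCS3 -0.32, PRDX1 -0.11, TXN -0.10, MT-CO3 -0.24, RPS12 -0.20, RPS18 -0.23 and IER3 -0.14. On FPKM with quantile normalization PRDX1 had -0.0039 and IER3 -0.047, and with length offsets MT-CO3 had -0.000630 and IER3 -0.039. Among alternative values of the named genes, 1112 kept direction and call, 43 changed sign, 7 lost a call and 3 gained one. For the 11 called lists, 169 of 216 alternative values kept direction and call, 45 lost the call and 2 were called the other way; for the 27 others, 48 of 557 gained a call in their direction and 2 in the other, over 13 lists. The cause of these differences was not tested.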

Other observations

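The tests with length offsets, of summed counts, and of the ratio of VIM to collagen were chosen after the results were seen, as was the use of the fit without TGFb_TFA 3 to weigh the ribosomal list. Genes named in the first paragraph outside the lists were chosen after their values were seen.

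The following genes did not pass in edgeR over all 6 libraries and are given for their fitted values, in data with fewer unadjusted p under 0.05 (334) than the 913 expected by chance. LINC01709 had no count in any TGF-β library and 74, 90 and 157 counts with TFA (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.427), and DESeq2 called it (adjusted p = 6.87e-09). KYAT1, which encodes a kynurenine aminotransferase, had a log2 fold change of 1.52 (SE 0.25) and UGT1A4, a glucuronosyltransferase, 0.90 (SE 0.28). WNT5A had 0.87 (SE 0.25) and GDF15, a stress cytokine, 0.48 (SE 0.15). On the lower side EGR1 had -0.72 (SE 0.25), the glucose transporter SLC2A3 -0.39 (SE 0.12) and NDRG1 -0.52 (SE 0.15). SCHIP1 had 345 and 349 counts in TGFb_TFA 1 and 2 but 33 in TGFb_TFA 3, against 28 to 40 with TGF-β. DESeq2 also called KYAT1 and SCHIP1 higher (adjusted p = 0.00863 each), and edgeR called SCHIP1 without TGFb_TFA 3 (adjusted p = 0.0257).

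STBD1, which was called, and AL137782, which edgeR did not call, lie in loci where genes overlap. For STBD1, a length trend of the libraries is argued against, since with offsets for length its log2 fold change was 2.19 (95% interval 1.80 to 2.57). Reads placed on STBD1 in 1 group and on FAM47E-STBD1 in the other may account for the call. Counts summed over STBD1 and FAM47E-STBD1 differed by -0.02 on the log2 scale (95% interval -0.33 to 0.29). With FAM47E added, the summed counts of the 3 genes differed by 0.18, with an upper bound of 0.49. The fitted rise of FAM47E, which shares exon bases with FAM47E-STBD1, is open to the same placing of reads. For AL137782, length is argued against in the same way (1.43, interval 0.73 to 2.13), but an exchange of reads with UCHL3 or LMO7 and a rise of its own cannot be told apart, since the sums with UCHL3 (0.19, interval -0.31 to 0.68) and with LMO7 (0.095, interval -0.31 to 0.50) hold both 0 and what AL137782 alone would add (0.24 and 0.31). A switch in which transcripts the cells make at either locus stays open and was not tested.

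Over all libraries ribosomal protein genes were called higher with TFA by camera at the preset correlation, but not at the estimated one (adjusted p = 0.726). They were not higher without TGFb_TFA 3. The median of -0.14 without it, against 0.22 over all libraries, is consistent with that library alone setting the direction. With length offsets the median was 0.17 and 74.1% of members stayed above 0.5 of the original median, which leaves open how far the length trend is the cause. A difference in the culture of that library stays open and was not tested.

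Fitted values of VIM, COL1A1 and COL1A2 were above 0 with TFA, but none of the 3 passed in edgeR, and DESeq2 called VIM alone. The length trend is argued against, since with offsets their mean log2 fold change was 2.76, against 2.65 without. Fibroblast RNA as a source of both and an effect of TFA cannot be told apart: the ratio of VIM to COL1A1 plus COL1A2 counts differed 11.5-fold among the TFA libraries (5.39, 1.44 and 0.467), but how far it varies without added RNA stays unknown, since the 15.0-fold among the TGF-β libraries (21.8, 1.45 and 2.06) rests on TGFb 1 with 4 collagen counts. Fibroblast markers did not all follow COL1A1 from library to library. DCN (50 and 168 counts) and COL3A1 (84 and 202) were seen only in TGFb_TFA 2 and 3, the libraries with the most COL1A1. COL6A3 (101, 264 and 40 in TGFb_TFA 1 to 3), FBLN1 (152, 155 and 146, with 196 in TGFb 3) and THY1 (54, 90 and 52, with 76 in TGFb 3) did not follow COL1A1. Their fitted log2 fold changes were still above 0 (3.56, 0.73 and 0.96). Trace RNA from a second cell source for the collagens, with VIM from the DLD-1 cells, may remain as well, and was not tested.

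Of 10 splits of the 6 libraries into groups of 3, the real split called 2 genes and the highest of the others 1, so 1 split gave as many as the real one, itself. By genes at an unadjusted p under 0.05 the real split had 334, and 5 of the 9 others had more, up to 2007 for TGFb 1, TGFb 2 and TGFb_TFA 3 against the rest, so the libraries differ along other lines than treatment. With 10 splits a share under 0.05 cannot be reached.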
